A study of Mus musculus with 9 samples.

How the data were processed

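RNA of 9 samples of mouse embryonic stem cells (3 each with a control hairpin, a hairpin against Phf5a and a hairpin against Paf1) was measured on Affymetrix expression arrays. Per the labels' protocols, cells were transduced with lentiviruses, selected with 2 μg/mL puromycin for 72 h, and total RNA was isolated with a silica column kit; 125 ng of it was turned into cDNA and labelled with whole-transcript kits. The values used are the log2 expression values that the authors deposited, 1 per probe set and array. The software, the background correction, the normalization and the log base are not given in the sources used here. A log2 scale was inferred from the range of the values (4.35 to 13.7) and from nearly equal quartiles across arrays. If the base were another, fold changes and the counts of 2-fold changes would differ, and calls would not. Hybridization signal that is not specific to a gene compresses the changes of dim genes on such arrays. Scanner files, detection calls, scan dates and slides were not used here, so that no batch could be tested.

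Samples were assigned to groups and replicates from their titles. Nothing in the labels says that replicates came from separate cultures or transductions, so that p-values measure the spread between these samples, which may be technical. Each group has 1 hairpin, and off-target effects of a hairpin cannot be separated from those of its target.

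Of 33793 probe sets, 23521 had 1 gene symbol in the platform's annotation, 1814 had several and 8458 were not listed there. By the annotation's gene ID 23328 of the first kind were found in the RefSeq gene table, all with the same symbol. For each of 22180 genes the probe set with the highest mean over all arrays was kept. Probe sets with several or no listed genes were left out of the gene counts. No genome build is given for the array, and no coordinates are reported.

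The test was limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per group over all 9 arrays, which share 1 estimate of the spread, contrasts between groups, and Benjamini-Hochberg adjustment at 0.05. Of 406 genes in 18 lists fixed before the data were examined, 382 were measured. The lists were those of pluripotency, primed epiblast, trophectoderm, primitive endoderm, mesoderm, neuroectoderm, Hox, 2-cell-stage, p53, ATF4, interferon-stimulated, immediate early, cell cycle, SF3 and U2 splicing, Paf1 complex, elongation, fibroblast, and macrophage and blood genes. They were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison. With a correlation estimated per list, calls held only for immediate early genes and fibroblast markers in shPaf1. That correlation was estimated over all 9 arrays and was the same in every comparison. The shPhf5a arrays therefore also entered these tests of shPaf1, and the lists that held changed without shPhf5a replicate 2, as given below.

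Genes named in the text followed a rule fixed in advance. Phf5a, Paf1, Pou5f1, Sox2 and Nanog were always named. For each knockdown the 8 largest rises and 8 largest falls were taken, and the 5 and 5 for the direct comparison, among called genes whose arrays did not overlap between the groups and whose higher mean exceeded the median of all genes (6.70). Predicted or unnamed loci, small RNAs, and olfactory and vomeronasal receptor genes were left out, recognised by the start of their symbols or an ending in Rik. Probe sets of several genes were left out too. Rny3, a small RNA, and AF357399 have symbols outside those patterns and were kept. From each list up to 4 called members with the largest change were eligible, and of genes called in opposite directions the 4 with the largest difference. Further names are said to have been chosen later.

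The scripts were tested on simulated data of 22180 genes for shPhf5a against shControl, with 200 changed genes. Changes of 0.5, 1 and 2 log2 units were called in 80.6%, 97.0% and 100% of such genes, and 7 of 21980 unchanged genes were called. Of 18 simulated unshifted lists 0 were called, and a list shifted by 0.5 was called. Genes were simulated independently of each other, whereas the correlation estimated in the data reached 0.50 for the cell cycle list. The simulation therefore does not show how often lists of correlated genes are called wrongly. Chance agreement through shared controls came from 100 simulations of groups without change. Alternatives were quantile normalization, centring of each array, only genes above the median level, the mean over the probe sets of a gene, all probe sets, a trended and robust variance, array weights, a fit of only the 6 arrays compared, the replicate number as a block, an estimated correlation and fry for the lists, and leaving out each array in turn. Chosen after seeing the data were gene families defined by symbol, 6 fibroblast transcripts, the tests on shPhf5a replicate 2 and the estimated correlation without that array.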

Results

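Gene expression was measured on 9 Affymetrix arrays of mouse embryonic stem cells carrying a fluorescent reporter of Nanog (the NG4 line), which were grown on gelatin in medium with LIF, the cytokine that keeps such cells undifferentiated. The cells had received a lentivirus with a control hairpin (shControl), a hairpin against Phf5a (shPhf5a) or a hairpin against Paf1 (shPaf1), and each group holds 3 arrays. Phf5a is a PHD-finger protein and a subunit of the SF3b splicing complex. Paf1 is the subunit that names the Paf1 complex, which travels with elongating RNA polymerase II. The title of the series places Phf5a in the control of transcriptional elongation in pluripotency, so that the comparisons ask what each knockdown did to the transcriptome and how far the responses resembled each other. The deposited table holds 33793 probe sets per array, and 22180 genes were tested. Array medians lay between 6.22 and 6.31 log2 units. The precision of every value is limited by the number of arrays.

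Both hairpins lowered their target. Phf5a fell by 1.24 log2 units in the shPhf5a arrays (SE 0.16, n = 3 arrays per group, 2.36-fold, limma adjusted p = 0.00024), to 34.4%, 55.9% and 39.6% of the control mean in replicates 1, 2 and 3. Paf1 fell by 1.39 in the shPaf1 arrays (SE 0.08, 2.62-fold, adjusted p = 1.73e-06), to 37.7%, 38.9% and 38.0%. Each target was also lower in the other knockdown. Phf5a fell by 0.57 in shPaf1 (SE 0.16, adjusted p = 0.0183), to between 62.0% and 76.2% of the control mean, and Paf1 fell by 0.25 in shPhf5a (SE 0.08, adjusted p = 0.0267). Those cross effects were the weaker calls. The first lost significance without shControl replicate 2, shPaf1 replicate 1 or shPaf1 replicate 2 (adjusted p from 0.0632 to 0.0742). The second lost it without shControl replicate 1 or 2 or shPhf5a replicate 1 or 3 (0.0737 to 0.0867), and also in a fit of only the 6 arrays compared (0.067).

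The core pluripotency factors responded unequally. Nanog fell by 0.84 log2 units in shPaf1 (SE 0.06, 1.79-fold, adjusted p = 4.2e-06) and by 0.25 in shPhf5a (SE 0.06, adjusted p = 0.00534), and the difference between the knockdowns passed the test (0.59, adjusted p = 5.43e-05). Pou5f1, which encodes Oct4, fell by 0.59 in shPhf5a (SE 0.11, 1.51-fold, adjusted p = 0.00174). In shPaf1 it fell by 0.33 (SE 0.11, adjusted p = 0.0391), a call that was lost in 7 of the 9 fits that left out 1 array (adjusted p from 0.0561 to 0.11; shControl replicates 1, 2 and 3, shPhf5a replicate 3, and shPaf1 replicates 1, 2 and 3). It was also lost when all probe sets were tested (adjusted p = 0.052). The difference in Pou5f1 between the knockdowns did not pass (-0.26, adjusted p = 0.104), but it passed with array weights (adjusted p = 0.014) and without shPhf5a replicate 2 (-0.40, adjusted p = 0.00249). Sox2 did not pass against the control in either knockdown (0.11 with adjusted p = 0.0709 in shPhf5a, and -0.06 with adjusted p = 0.311 in shPaf1), but in shPhf5a it passed after quantile normalization (0.17, adjusted p = 0.0143). The difference in Sox2 between the knockdowns passed (0.18, adjusted p = 0.0122).

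**Figure D1:**
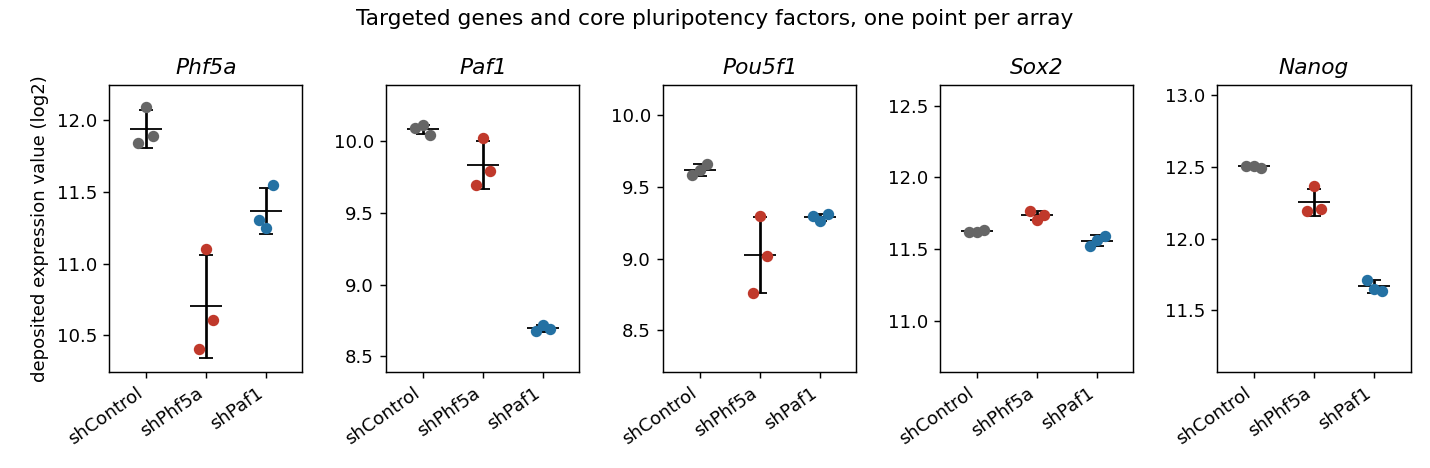
Deposited expression values (log2) of Phf5a, Paf1, Pou5f1, Sox2 and Nanog in the 9 arrays, 1 point per array, with horizontal marks for group means and bars for the SD (n = 3); every panel spans the same number of log2 units and no axis starts at 0. Phf5a is lowest in shPhf5a and Paf1 in shPaf1, and replicate 2 has the highest Phf5a of the shPhf5a arrays (55.9% of the control mean).

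The hairpin against Phf5a was compared with the control hairpin to find the genes whose levels differed. The largest rises were those of Ahnak2 (3.80 log2 units, SE 0.20), Tdpoz2 (3.30, SE 0.29), Sp110 (2.89, SE 0.22), Gata2 (2.84, SE 0.14), a transcription factor of blood and trophoblast, Tdpoz3 (2.74, SE 0.27), the small heat shock protein Cryab (2.68, SE 0.17), the paraspeckle RNA Neat1 (2.65, SE 0.16) and the carboxylesterase Ces2g (2.62, SE 0.20). The largest falls were those of Rny3, a small Y RNA (-2.10, SE 0.20), the transcription factor Tcf15 (-2.04, SE 0.22), the keratin Krt17 (-2.01, SE 0.20), the phospholipase Pla2g1b (-1.97, SE 0.22), Hpdl (-1.92, SE 0.16), the PCNA-associated factor Pclaf (-1.87, SE 0.21), Catsperz (-1.86, SE 0.21) and Rragb (-1.75, SE 0.23). All of these had adjusted p of 0.00027 or less. In total 3713 genes were higher and 4593 lower (37.4% of the genes tested), and 459 and 270 of them by at least 2-fold. The count of 2-fold falls depended on single arrays, being 172 without shPhf5a replicate 1 and 464 without shPhf5a replicate 2. In 45.8% of genes the 3 arrays of one group all lay above those of the other, where chance gives 10%.

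Genes of the 2-cell-stage embryo and targets of p53 rose. Of 22 measured 2-cell-stage genes 20 were higher and 1 lower, both over all genes and adjusted over the list alone, with Tdpoz2, Sp110, Tdpoz3 and Usp17le (2.59, SE 0.15) leading. Tdpoz, Usp17l, Zscan4 and Pramel genes lie in families of near-identical members, so that a probe set may read several of them. Of 25 p53 targets, 21 were higher and 1 lower, again also adjusted over the list alone. Ddit4l rose by 2.06 (SE 0.11), the antiproliferative gene Btg2 by 1.86 (SE 0.08), Dcxr by 1.78 (SE 0.07) and the kinase Plk2 by 1.71 (SE 0.07). In limma's camera test both lists passed (adjusted p = 6.45e-12 and 3.7e-16), and neither did with an estimated correlation (adjusted p = 0.211 for the 2-cell-stage genes and adjusted p = 0.185 for the p53 targets). Mean changes in replicates 1, 2 and 3 were 1.57, 1.09 and 1.56 for the 2-cell-stage genes and 0.98, 0.85 and 1.01 for the p53 targets.

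Markers of extraembryonic lineages rose as well. Of 18 trophectoderm genes 14 were higher and 1 lower, and the same numbers were found adjusted over the list alone. The keratins Krt18 and Krt8 rose by 2.49 (SE 0.19) and 1.98 (SE 0.21), and the transcription factors Hand1 and Ascl2 by 1.87 (SE 0.18) and 1.72 (SE 0.14). The list passed at adjusted p = 1.16e-07, and had adjusted p = 0.211 with an estimated correlation. Of 21 primitive endoderm genes 11 were higher and 1 lower (11 and 2 adjusted over the list alone), led by Gata6 (1.78, SE 0.20), Dab2 (1.19, SE 0.13), Lrp2 (1.13, SE 0.12) and Lamb1 (0.60, SE 0.05), with adjusted p = 0.00301 and, with an estimated correlation, adjusted p = 0.557. Mean changes in replicates 1, 2 and 3 were 1.01, 0.72 and 0.87 for trophectoderm and 0.52, 0.22 and 0.33 for primitive endoderm.

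The pluripotency and cell cycle lists fell. Of 35 pluripotency genes 20 were lower and 3 higher (20 and 4 adjusted over the list alone). The Nodal antagonists Lefty2 and Lefty1 fell by 1.41 (SE 0.19) and 1.22 (SE 0.21), Tcl1 by 1.10 (SE 0.17) and the nuclear receptor Nr0b1 by 0.87 (SE 0.09). That list passed at adjusted p = 0.022, and had adjusted p = 0.557 with an estimated correlation. It did not pass after quantile normalization (0.104), after centring of each array (0.0529) or among genes above the median level (0.0806), and ranged from 0.00154 to 0.104 over 18 settings that kept the preset correlation, of which 15 passed. Of 28 mitosis and cell cycle genes 17 were lower and 3 higher (19 and 3 adjusted over the list alone), with falls of the cyclins Ccne1 by 1.18 (SE 0.15) and Ccnd1 by 0.74 (SE 0.12) and of Cdk2 by 0.70 (SE 0.11), while the proliferation marker Mki67 rose by 0.54 (SE 0.06). The list had adjusted p = 0.00301, and adjusted p = 0.557 with an estimated correlation. Mean changes in replicates 1, 2 and 3 were -0.39, -0.15 and -0.32 for pluripotency and -0.35, -0.11 and -0.28 for the cell cycle.

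The other lists did not pass in shPhf5a, although single members changed. Among 20 SF3 and U2 splicing factors, the complex that Phf5a belongs to and its neighbours, 5 were higher and 10 lower (6 and 13 adjusted over the list alone; list adjusted p = 0.398). Dnajc8 fell by 1.47 (SE 0.16), Sf3b6 by 0.90 (SE 0.10) and Snrpa1 by 0.86 (SE 0.10), and Rbm17 rose by 0.62 (SE 0.06). Of the 5 Paf1 complex partners Ctr9 rose by 1.14 (SE 0.08), Rtf1 fell by 0.65 (SE 0.06) and Cdc73 fell by 0.25 (SE 0.05), and the list had adjusted p = 0.784 with the same counts of 1 higher and 2 lower adjusted over the list alone. Of 26 elongation factors 11 were higher and 5 lower (12 and 6 adjusted over the list alone; adjusted p = 0.107, which became 0.00942 after quantile normalization and 0.0348 without shPhf5a replicate 1, with a range from 0.00942 to 0.193 over the 18 settings of the camera test that kept the preset correlation; adjusted p = 0.557 with an estimated correlation), with Nelfa at 0.54 (SE 0.05), Setd2 at 0.51 (SE 0.05) and Nelfb at -0.42 (SE 0.06). Of 21 immediate early genes 9 were higher and 5 lower (9 and 6 adjusted over the list alone; adjusted p = 0.26), with Ccn1 at 2.16 (SE 0.16), Jun at 2.07 (SE 0.13) and Ier2 at -1.01 (SE 0.15). Primed epiblast genes were higher in 3 and lower in 7 of 14 (the same adjusted over the list alone; adjusted p = 0.452), with Wnt8a at 1.04 (SE 0.10) and the DNA methyltransferase gene Dnmt3b at -0.82 (SE 0.15).

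The lists of ATF4 targets (3 higher and 12 lower of 24, 4 and 12 adjusted over the list alone; adjusted p = 0.169), neuroectoderm (4 and 8 of 19, the same adjusted over the list alone; adjusted p = 0.452), mesoderm (5 and 2 of 19, 4 and 2 adjusted over the list alone; adjusted p = 0.452), interferon-stimulated genes (1 and 7 of 19, the same adjusted over the list alone; adjusted p = 0.239) and Hox genes (3 and 2 of 36, 2 and 1 adjusted over the list alone; adjusted p = 0.796) did not pass in shPhf5a either. Among the ATF4 targets Ddit4 rose by 1.56 (SE 0.06) and the amino acid transporter gene Slc7a3 was at -1.32 (SE 0.12). Among neuroectoderm genes Gbx2 was at -1.17 (SE 0.12) and Cdh2 at 1.07 (SE 0.06), and among mesoderm genes Wnt3 rose by 1.43 (SE 0.13). Irf9 was at -0.60 (SE 0.06) and Hoxb9 at 1.10 (SE 0.10). Fibroblast markers were higher in 3 and lower in 2 of 20 (the same adjusted over the list alone; adjusted p = 0.784), and macrophage and blood markers lower in 3 of 10 (2 adjusted over the list alone; adjusted p = 0.169). With fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, 5 of the lists that did not pass had adjusted p under 0.05. They were elongation factors (0.00189), immediate early genes (0.000468) and mesoderm genes (0.00964), all upward, and interferon-stimulated genes (0.000577) and macrophage and blood markers (0.0114), both downward. Median, mean and direction of the camera test differed in sign for immediate early genes (median -0.08, mean 0.19, test upward), Hox genes (-0.03, 0.04, upward), Paf1 complex partners (-0.08, 0.06, downward) and fibroblast markers (-0.04, -0.01, upward).

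**Figure D2:**
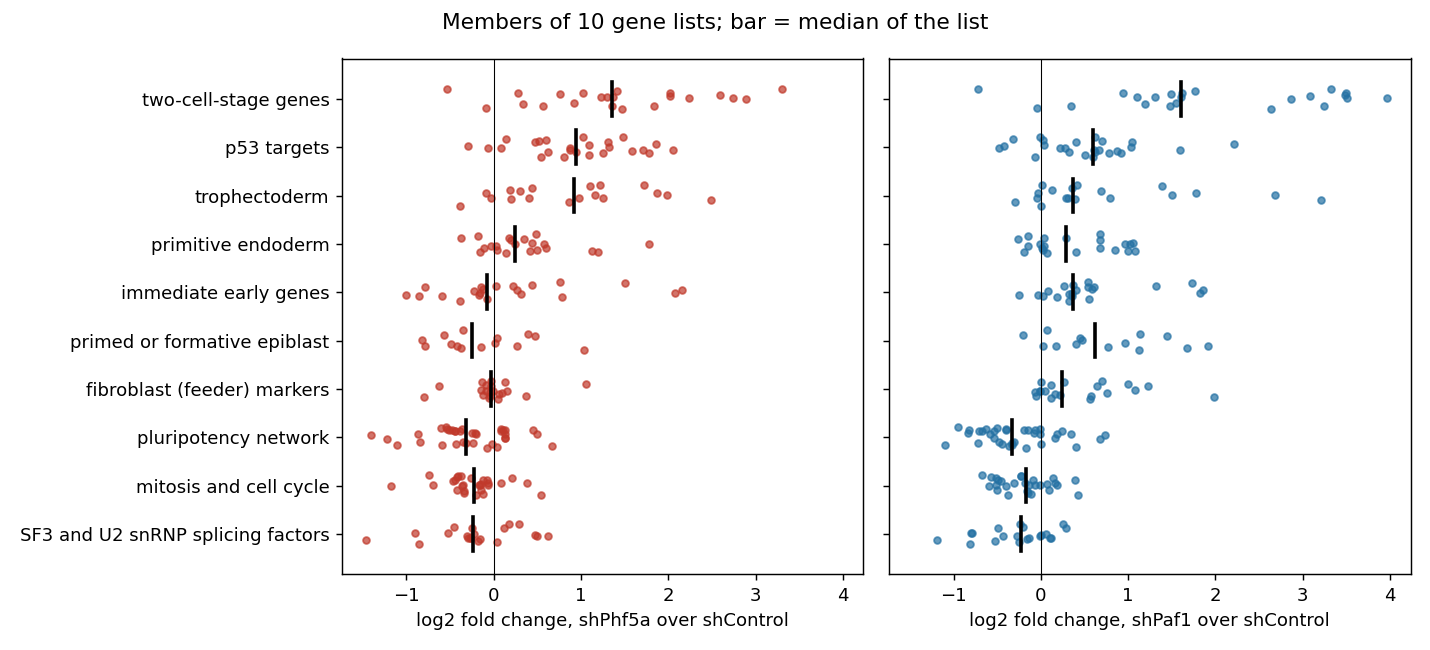
Log2 fold changes of the measured members of 10 gene lists in shPhf5a (left) and shPaf1 (right) over shControl, 1 point per gene, with a bar at the median of the list; points are spread vertically at random within a list. The medians of the 2-cell-stage list are 1.36 in shPhf5a and 1.61 in shPaf1, and those of the primed epiblast list lie on opposite sides of 0 (-0.24 and 0.63).

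Knockdown of Paf1 was compared with the same control arrays. The largest rises were those of the protease inhibitor gene Serpinb9e (4.07 log2 units, SE 0.24), Tdpoz3 (3.96, SE 0.27), Usp17la (3.50, SE 0.18), Tdpoz4 (3.49, SE 0.12), the matrix protein gene Thbs1 (3.49, SE 0.13), Usp17le (3.49, SE 0.15), Tnfrsf23 (3.36, SE 0.19) and Tdpoz2 (3.32, SE 0.29). The largest falls were those of Catsperz (-2.39, SE 0.21), Accsl (-2.12, SE 0.15), Mrpl47, a protein of the mitochondrial ribosome (-2.06, SE 0.18), Oas1g (-2.03, SE 0.21), AF357399 (-2.02, SE 0.21), Rny3 (-1.96, SE 0.20), Zcwpw1 (-1.91, SE 0.06) and the mitochondrially encoded ND6 (-1.85, SE 0.13). Oas1g and AF357399 had close means in every group (7.59 and 7.61 in shControl, 6.26 and 6.33 in shPhf5a, 5.56 and 5.58 in shPaf1). They may be 1 signal, which was not tested. All of the rises and falls named had adjusted p of 5.64e-05 or less. In total 3983 genes were higher and 3947 lower (35.8%), and 423 and 217 of them by at least 2-fold. In 48.3% of genes the arrays of the groups did not overlap, where chance gives 10%.

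Genes of the 2-cell stage rose in shPaf1, with 20 of 22 higher and 1 lower over all genes and adjusted over the list alone, led by Tdpoz3, Usp17la, Tdpoz4 and Usp17le (camera adjusted p = 1.17e-13, and adjusted p = 0.155 with an estimated correlation). Of 25 p53 targets 18 were higher and 3 lower, the same adjusted over the list alone, with rises of Btg2 (2.21, SE 0.08), Plk2 (1.60, SE 0.07), Trp53inp1 (1.04, SE 0.07) and the cell cycle inhibitor Cdkn1a (1.04, SE 0.09). The list had adjusted p = 1.72e-06, and adjusted p = 0.244 with an estimated correlation. Of 18 trophectoderm genes 10 were higher and 1 lower (13 and 1 adjusted over the list alone), with Krt18 (3.21, SE 0.19), Krt8 (2.68, SE 0.21) and Hand1 (1.78, SE 0.18) leading (adjusted p = 0.000123, and adjusted p = 0.275 with an estimated correlation). Of 21 primitive endoderm genes 11 were higher and 0 lower, also adjusted over the list alone, with the basement membrane collagens Col4a2 and Col4a1 at 1.08 (SE 0.11) and 1.06 (SE 0.10) and Gata6 at 1.03 (SE 0.20). That list had adjusted p = 0.00159, and adjusted p = 0.44 with an estimated correlation.

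Genes of the primed epiblast, the state that follows naive pluripotency, rose in shPaf1, while the pluripotency list fell. Of 14 primed genes 10 were higher and 0 lower (10 and 1 adjusted over the list alone). Lef1, a transcription factor of the Wnt pathway, rose by 1.92 (SE 0.13), the kinase gene Pim2 by 1.67 (SE 0.13), the tight junction gene Cldn6 by 1.45 (SE 0.11) and the transcription factor Otx2 by 1.14 (SE 0.09). The list had adjusted p = 3.07e-05, and adjusted p = 0.244 with an estimated correlation. Of 35 pluripotency genes 21 were lower and 5 higher (22 and 5 adjusted over the list alone). Tcl1 fell by 1.10 (SE 0.17), Prdm14 by 0.95 (SE 0.10) and Zfp42, which encodes Rex1, by 0.82 (SE 0.07), and the list had adjusted p = 0.000181 (adjusted p = 0.337 with an estimated correlation).

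Immediate early genes and fibroblast markers rose in shPaf1, the only lists of this comparison that also passed with an estimated correlation (adjusted p = 0.0478 for both). Of 21 immediate early genes 15 were higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 1.06e-06), with Ccn1 at 1.86 (SE 0.16), Jun at 1.82 (SE 0.13), Ccn2 at 1.73 (SE 0.05) and the RNA-binding protein gene Zfp36 at 1.31 (SE 0.06). Of 20 fibroblast markers 11 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 2.42e-05), with the actin gene Acta2 at 1.99 (SE 0.07), the actin-binding Tagln at 1.23 (SE 0.15), the chemokine Ccl2 at 1.08 (SE 0.09) and the matrix protease Mmp2 at 1.00 (SE 0.06). Among 6 matrix transcripts that fibroblasts make in quantity, chosen after the result of the list had been seen, Dcn rose by 0.57 (SE 0.06) and Col1a1 by 0.22 (SE 0.07), and Col1a2, Col3a1, Lum and Postn did not pass (0.00, 0.11, 0.04 and 0.16). All but Col1a1 (7.14) had dim means in shPaf1, from 4.86 for Lum to 6.09 for Col3a1, with Dcn at 5.87. These lie below the median of all genes (6.70), where changes may be compressed. The fibroblast list mean was 0.47, 0.48 and 0.44 above the control mean in shPaf1 replicates 1, 2 and 3, and that of the primed epiblast list 0.70, 0.77 and 0.76. The immediate early and fibroblast lists no longer passed with an estimated correlation when shPhf5a replicate 2 was left out, an alternative chosen after seeing the data (adjusted p = 0.0738 for each). Primed epiblast and 2-cell-stage genes passed in shPaf1 under that alternative (adjusted p = 0.0412 and 0.0224), although the array left out belongs to neither group compared.

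Cell cycle, splicing and elongation lists passed in shPaf1 as well. Of 28 cell cycle genes 13 were lower and 3 higher (14 and 4 adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.56 with an estimated correlation), including Ccnd1 by a fall of 0.67 (SE 0.12), Ccne1 by 0.59 (SE 0.15), Cdc25c by 0.57 (SE 0.11) and Birc5 by 0.52 (SE 0.06). Of 20 SF3 and U2 factors 10 were lower and 2 higher (11 and 2 adjusted over the list alone; adjusted p = 0.009, and adjusted p = 0.44 with an estimated correlation), with falls of Dnajc8 by 1.19 (SE 0.16), Snrpa1 by 0.81 (SE 0.10), Sf3b6 by 0.80 (SE 0.10) and U2af1 by 0.79 (SE 0.09). Of 26 elongation factors 12 were higher and 7 lower, also adjusted over the list alone (adjusted p = 0.0354, and adjusted p = 0.376 with an estimated correlation), with Mllt1 at 0.80 (SE 0.05), Supt5 at 0.71 (SE 0.05), Supt6 at 0.70 (SE 0.04) and Nelfa at 0.57 (SE 0.05). The cell cycle call was lost after quantile normalization (0.185) and among genes above the median level (0.0585), that of the splicing factors after quantile normalization (0.0507), and that of the elongation factors among genes above the median level (0.115), with the replicate number as a block (0.0518) and without shPaf1 replicate 2 (0.0658). Over the 18 settings that kept the preset correlation, the adjusted p ranged from 0.00318 to 0.185 for the cell cycle, from 0.00595 to 0.0507 for the splicing factors and from 0.013 to 0.115 for the elongation factors.

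The remaining lists did not pass in shPaf1. Of the 5 Paf1 complex partners Ctr9 rose by 0.74 (SE 0.08), Rtf1 rose by 0.27 (SE 0.06) and Wdr61 fell by 0.37 (SE 0.04), with 2 higher and 1 lower also adjusted over the list alone (list adjusted p = 0.325). ATF4 targets were higher in 4 and lower in 10 of 24, also adjusted over the list alone (adjusted p = 0.102), with Ddit4 at 1.32 (SE 0.06), Ddit3 at 1.11 (SE 0.08) and a fall of Cth by 0.98 (SE 0.06). Of 19 neuroectoderm genes 4 were higher and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.76), with Cdh2 at 1.75 (SE 0.06), Nes at 1.61 (SE 0.05) and falls of Tubb3 by 0.89 (SE 0.08) and Pax6 by 0.76 (SE 0.13). Mesoderm genes were higher in 5 and lower in 1 of 19 (7 and 2 adjusted over the list alone; adjusted p = 0.128, and 0.0443 among genes above the median level, with a range from 0.0443 to 0.215 over the 18 settings that kept the preset correlation; adjusted p = 0.319 with an estimated correlation), with Wnt3 at 1.42 (SE 0.13) and Snai2 at 1.14 (SE 0.15). Of 36 Hox genes 7 were higher and 1 lower (5 and 0 adjusted over the list alone; adjusted p = 0.12), led by Hoxb9 at 0.98 (SE 0.10) and Hoxc13 at 0.88 (SE 0.08). Interferon-stimulated genes (2 higher and 5 lower of 19, the same adjusted over the list alone; adjusted p = 0.918) and macrophage and blood markers (1 and 1 of 10, the same adjusted over the list alone; adjusted p = 0.76) did not pass. With fry 5 of these lists had adjusted p under 0.05, namely mesoderm (0.0015), neuroectoderm (0.0046), Hox genes (0.00647) and Paf1 complex partners (0.0248) upward and ATF4 targets (0.0248) downward. The camera test was upward for neuroectoderm at a mean of 0.09 and a median just below 0, and downward for interferon-stimulated genes at a median of 0.02.

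**Figure D3:**
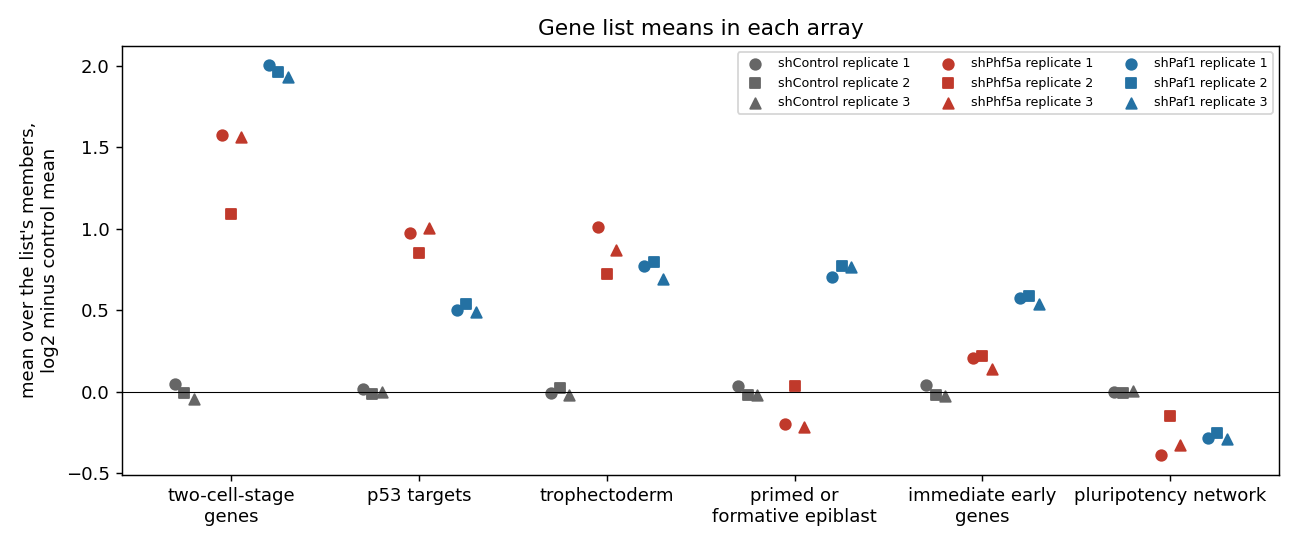
Mean over the members of 6 gene lists in each of the 9 arrays, as log2 difference from the control mean, with colours for the groups and point shapes for the replicates. In shPhf5a the replicate 2 array lies nearer to 0 than the other arrays of its group for 2-cell-stage genes (1.09 against 1.57 and 1.56), and the shPaf1 arrays of the primed epiblast list lie between 0.70 and 0.77.

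The responses to the 2 knockdowns shared many calls. Of the genes tested, 2352 were higher in both, 2665 were lower in both and 460 were called in opposite directions. Independent lists of the same sizes would share 667 and 817 genes, with 1486 in opposite directions. Both comparisons use the same 3 control arrays, which are too few to be split into sets of at least 2 arrays, so that part of the excess may come from them. Simulated unchanged groups against shared controls gave 0 shared calls. Groups without change have hardly any calls to share, so that this count cannot show how much the shared controls add. The log2 fold changes correlated across genes, which are not independent replicates, with r = 0.682, where the simulations gave a median r of 0.498. The signs were equal in 72.9% of genes against 66.6%. The covariance was 0.106 against a median of 0.00392 and a maximum of 0.00419 in the simulations. This argues against the spread between control arrays as the main source of the covariance. A deviation common to all 3 control arrays was not simulated and stays open. The count of opposite calls was 293 without shControl replicate 1, 301 without shControl replicate 2 and 734 with array weights.

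**Figure D4:**
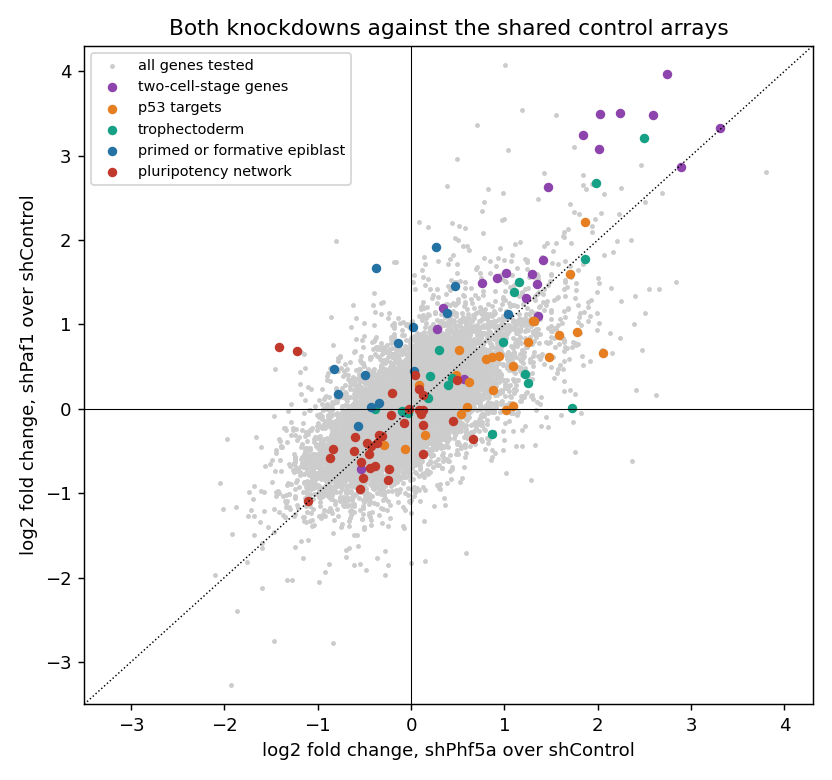
Log2 fold change over shControl of each gene tested (grey) in shPhf5a (x axis) and shPaf1 (y axis), with the members of 5 gene lists in colour and a dotted line where the changes are equal. Pluripotency genes lie mostly at the lower left, with Lefty2 (-1.41 and 0.73) above the line of no change in shPaf1, and 2-cell-stage genes lie mostly at the upper right.

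The knockdowns were also compared directly, since a call in one and not in the other does not show a difference. Here 2806 genes were higher and 3624 lower in shPhf5a than in shPaf1 (29.0%), and 159 and 199 of them by at least 2-fold. Higher in shPhf5a were Ces2g (2.46 log2 units, SE 0.20), Dglucy (2.27, SE 0.09), the phosphatase gene Alppl2 (2.20, SE 0.15), the gluconeogenic enzyme gene Fbp1 (1.89, SE 0.08) and Mst1 (1.87, SE 0.14). Higher in shPaf1 were Serpinb9e (-3.07, SE 0.24), Acta2 (-2.79, SE 0.07), Tnfrsf23 (-2.66, SE 0.19), Frg2f8 (-2.47, SE 0.09) and the matrix protease gene Mmp9 (-2.26, SE 0.12). The largest differences among genes called in opposite directions against the control were those of Acta2 (-0.80 in shPhf5a and 1.99 in shPaf1), Dglucy (1.76 and -0.51), Lefty2 (-1.41 and 0.73) and Pim2 (-0.38 and 1.67). The fall of Pim2 in shPhf5a had adjusted p = 0.0426 and was lost in 8 of the 9 fits that left out 1 array (adjusted p from 0.0589 to 0.157), the fit without shPhf5a replicate 2 being the exception. It was also lost when all probe sets were tested (0.0571) and in a fit of only the 6 arrays compared (0.1).

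Gene lists separated the knockdowns too. Primed epiblast genes were lower in shPhf5a than in shPaf1 in 13 of 14 and higher in 0 (the same adjusted over the list alone; camera adjusted p = 1.69e-08, and adjusted p = 0.134 with an estimated correlation). Of 25 p53 targets 19 were higher and 2 lower in shPhf5a, the same adjusted over the list alone (adjusted p = 3.36e-09, and adjusted p = 0.147 with an estimated correlation). Fibroblast markers were lower in 11 and higher in 1 of 20, the same adjusted over the list alone (adjusted p = 0.000209, and adjusted p = 0.134 with an estimated correlation). Of 22 genes of the 2-cell stage, 13 were lower and 0 higher (14 and 2 adjusted over the list alone; adjusted p = 0.000749, and adjusted p = 0.616 with an estimated correlation). Immediate early genes were lower in 13 and higher in 2 of 21, the same adjusted over the list alone (adjusted p = 0.00143, and adjusted p = 0.134 with an estimated correlation). The other 13 lists did not pass (adjusted p from 0.122 to 0.934). Among them, pluripotency genes passed without shPhf5a replicate 1 (0.022, with adjusted p = 0.822 with an estimated correlation over all arrays). Neuroectoderm genes passed when all probe sets were tested (0.0415, with adjusted p = 0.786 with an estimated correlation over the genes tested). With fry 8 of the 13 had adjusted p under 0.05. The direction of fry was upward in shPhf5a against shPaf1 for trophectoderm genes (0.0293), although 4 of 18 were called higher and 6 lower, the same adjusted over the list alone. It was upward too for SF3 and U2 factors (0.0297; 7 of 20 higher and 4 lower, 8 and 4 adjusted over the list alone), at a median of -0.02 and a mean of 0.08. It was downward for neuroectoderm and interferon-stimulated genes (0.00322 for both), Paf1 complex partners (0.00972), elongation factors (0.0125), Hox genes (0.0202) and macrophage and blood markers (0.0304). Of the 5 Paf1 complex partners 2 were higher and 2 lower, also adjusted over the list alone, at a median of 0.04 and a mean of -0.10. Of 26 elongation factors 7 were higher and 8 lower (8 and 11 adjusted over the list alone). The camera test was upward for pluripotency genes at a mean of -0.01 and a median of 0.04, and for ATF4 targets at a mean of -0.01 and a median of -0.07.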

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

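The tests on shPhf5a replicate 2 and the gene families defined by symbol were chosen after the patterns had been seen, and the reason given for leaving small RNA recovery open was noted after the microRNA value had been seen.

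The effects of the 2 knockdowns against the control differed for 5 lists, with mean differences (shPhf5a minus shPaf1) of -0.870 for primed epiblast genes, -0.555 for 2-cell-stage genes, 0.437 for p53 targets, -0.377 for immediate early genes and -0.480 for fibroblast markers. The difference was itself tested, and these calls did not hold with an estimated correlation. In opposite directions against the control, 460 genes were called. Their direct differences passed as well, which their selection by opposite calls made nearly certain and which therefore adds no evidence. The largest of those differences were those of Acta2 (-2.79), Dglucy (2.27), Lefty2 (-2.14) and Pim2 (-2.04).

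Probe sets outside the gene counts also changed. Of 8458 probe sets with no listed gene, 1509 changed in shPhf5a and 1499 in shPaf1, and of 1814 that name several genes, 785 and 648. All 7 probe sets of the Zscan4 family, genes of the 2-cell stage that share sequence, were higher in both knockdowns, by 0.76 to 1.41 log2 units in shPhf5a and by 1.08 to 1.77 in shPaf1. Most of these probe sets name 1 gene and were already part of the gene counts and of the 2-cell-stage list. Only those that name several genes lie outside them.

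The shPhf5a array of replicate 2 lay between the controls and the other arrays of its group: on the first principal component, with 56.4% of the variance, it had 6.16, against 26.8 and 22.6 for replicates 1 and 3 and -36.7 to -35.2 for the controls. Control cells or RNA mixed into the sample would give large and small rises the same share on the linear scale. The median share was 0.575 for rises of over 4-fold and 0.685 for rises of 2- to 2.8-fold, a difference of -0.110 (95% bootstrap interval -0.155 to -0.0542). Among rises the shares were therefore unequal, whereas mixing alone would make them equal. The shares come from 1 array, so that the interval measures a spread over genes and not between arrays. Falls went the other way, with 0.759 for falls of over 2.8-fold and 0.701 for those of 2- to 2.8-fold. On the log2 scale the shares were 0.752 and 0.762 for these rises and 0.629 and 0.605 for these falls. Mixing would give falls lower log2 shares than rises, and they were lower, so that the shares cannot decide on it. A weaker knockdown stays open: Phf5a itself fell by 0.840 log2 units in replicate 2, against 1.54 and 1.34 in the others. Mixing would also make Phf5a fall less, so that these values cannot tell it from a weaker knockdown. As both tests were chosen after the pattern was seen, the weaker knockdown is a hypothesis, and a different time or dose of infection was not tested.

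Transcripts of the mitochondrial ribosome, complex I and the proteasome, families defined by symbol, were lower in both knockdowns (118 of 152 genes in shPhf5a and 112 in shPaf1, with medians of -0.44 and -0.42). A bias that depends on expression level would lower genes of matched mean expression about as much, but random lists matched on mean expression had medians of only -0.07 in shPhf5a and -0.05 in shPaf1, which argues against it as the whole cause. The distance of the families from percentile 2.5 of those lists (-0.294 for the nearer) is partly set by their choice after their values were seen. The medians of the families kept their sign under both scalings tried, and the camera call of each was lost with an estimated correlation. A slower growth of the cells, a shared effect of the hairpins and a biological effect of the knockdowns were not tested.

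Probe sets of snoRNAs and scaRNAs were lower in shPaf1 (47 of 78 lower and 4 higher, median -0.52; camera adjusted p = 9.77e-12, and adjusted p = 0.188 with an estimated correlation). Poorer recovery of small RNA was set against 85 microRNA probe sets, whose median was -0.0471 (95% bootstrap interval -0.111 to 0.0177), above the bound of -0.258 that had been written beforehand as evidence against it. Although that bound was met, it was wrong by design, since whole-transcript labelling of column-purified RNA lets a microRNA probe set read the long primary transcript, and recovery of small RNA cannot be told apart from a real fall. Lower transcription of the host genes may contribute: the changes of 63 snoRNAs followed those of their 49 hosts with a Spearman correlation of 0.352 (permutation p = 0.0043, adjusted p = 0.0043 over both knockdowns; Pearson 0.274), although snoRNAs that share a host are not independent, a probe set in an intron can read unspliced host RNA, and 50 of the 63 lay below their host. The correlation was as high in shPhf5a (0.367, permutation p = 0.0032), where the snoRNA list did not pass (median -0.14), so that it is not particular to the knockdown with the fall.

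For each comparison, the real split of the 6 arrays was set against the other splits into 3 and 3. The real splits called 8306, 7930 and 6430 genes and the highest other split called 0 in each case, so that 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Every other split mixes arrays of both groups, so that a difference between them becomes spread within the split groups. The 0 calls there largely follow from that, whatever the cause of the difference.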

How the results depend on the processing

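The estimated correlation without shPhf5a replicate 2 was chosen after seeing the data. Across all alternatives no called value changed sign, and 25 changes of sign concerned values that did not pass in either fit. Total counts per direction stayed within 1.5 times under every alternative, and no scaling moved the median of all genes by over 0.1. The scalings, quantile normalization and centring of each array, align arrays whose medians were already close. A small move of the median was therefore largely fixed in advance. Labelling also started from the same amount of RNA for every array. A change shared by most genes could thus not be seen, and higher and lower are relative to the other genes on the arrays.

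With all probe sets tested, which adds probe sets, 722 instead of 459 rose by at least 2-fold in shPhf5a, 646 and 508 instead of 423 and 217 rose and fell in shPaf1, and 358 and 316 instead of 159 and 199 in the direct comparison. Array weights gave 734 opposite calls instead of 460; the cause was not tested. Paf1 in shPhf5a lost its call in a fit of only the 6 arrays compared (-0.246, adjusted p = 0.067), which has fewer samples. Lists passing in shPhf5a, shPaf1 and the direct comparison numbered 0, 2 and 0 with the estimated inter-gene correlation, and 2, 2 and 2 with it and without shPhf5a replicate 2, when 2-cell-stage genes and p53 targets passed in shPhf5a (adjusted p = 0.0156 for both), primed epiblast and 2-cell-stage genes in shPaf1 (0.0412 and 0.0224), and primed epiblast genes and p53 targets in the direct comparison (0.0237 and 0.0358). Fry, which does not compare a list with other genes, gave 11 in shPhf5a, 16 in shPaf1 and 13 in the direct comparison.

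With 1 array left out, Paf1 in shPhf5a ranged from -0.338 to -0.177, Phf5a in shPaf1 from -0.664 to -0.497, the count of opposite calls from 293 to 660, and the count of 2-fold falls in shPhf5a from 172 to 464; these fits have fewer samples. Of 193 results for named genes, 7 lost their call in at least 1 such fit: besides Paf1, Phf5a, Pou5f1 and Pim2, as given above, Cd79a and Hoxc12 in shPhf5a and Eomes in shPaf1. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated between -0.0578 and 0.106, those of other numbers between -0.181 and 0.102, and 1 of 9 arrays lay closest to its own number. With the replicate block, 3659 and 4551 genes were called in shPhf5a, 3958 and 3900 in shPaf1, and 2704 and 3551 in the direct comparison, and among the lists the elongation factors in shPaf1 no longer passed (adjusted p = 0.0518). Another background correction was not run, since it needs scanner files, and the level of signal over background behind each value is unknown.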

Other observations

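The gene families of this part, and with them their tests, were chosen by symbol after seeing the data. Ribosomal protein genes of the cytoplasm were lower in both knockdowns, with 31 of 60 lower and 0 higher in shPhf5a and 47 lower and 0 higher in shPaf1 (medians -0.21 and -0.41, with camera adjusted p = 0.000163 and 7.96e-15, and adjusted p = 0.518 and 0.146 with an estimated correlation). The Pramel genes, a family active in germ cells and early embryos whose members share sequence, were higher, with 13 of 30 higher in shPhf5a and 14 in shPaf1 and 0 lower (medians 0.15 and 0.19; camera adjusted p = 0.000302 and 8.13e-06, and adjusted p = 0.0576 and 0.0242 with an estimated correlation). Their median level was 5.39, below that of all genes (6.70). Pramel6 and Pramel7 are also in the 2-cell-stage list, so that the family is not separate from that list. Of 7 Serpinb9 genes, which lie in a cluster of similar members, 6 were higher in shPaf1 (median 1.71; adjusted p = 5.21e-06, and adjusted p = 0.118 with an estimated correlation). In shPhf5a 3 were higher and the family did not pass (median 0.15; adjusted p = 0.0665, and adjusted p = 0.518 with an estimated correlation). In the direct comparison 6 were lower in shPhf5a (adjusted p = 6.07e-06, and adjusted p = 0.17 with an estimated correlation). The medians of these families kept their sign under quantile normalization and centring of each array.

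Genes of small nucleolar RNA hosts (Snhg) were lower in 9 of 15 in shPaf1, with 0 higher (adjusted p = 1.07e-05, and adjusted p = 0.118 with an estimated correlation), and did not pass in shPhf5a, where 3 were higher and 5 lower and the median changed sign with centring of each array (0.03 and -0.01). All 10 mitochondrially encoded genes were higher in shPhf5a than in shPaf1, or 9 after quantile normalization (median 0.30, and 0.20 after quantile normalization; adjusted p = 1.14e-06, and adjusted p = 0.212 with an estimated correlation). Random lists matched on mean expression had a median of 0.18 in that comparison, and 95% of their medians lay between -0.0032 and 0.21, so that part of the difference was shared by genes of like brightness. Of 1105 olfactory receptor genes 25 were higher and 20 lower in shPhf5a, and 27 and 12 in shPaf1. With centring of each array the balance in shPhf5a turned, to 22 higher and 42 lower, and 22 and 15 were called in shPaf1.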
